A study of Mus musculus with 6 samples.

How the data were processed

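The series compares quadriceps muscle of 3 wild-type and 3 ERRγ-transgenic male mice at 8 weeks of age. Total RNA was extracted with Trizol and labelled with biotin as cRNA by the standard Affymetrix protocol, per the labels' protocols. The deposited values are MAS5 signal intensity on a linear scale, per the labels (the submitters' processing notes name MAS5, and its version and settings are not given in the sources used here). The deposited signals have a mean of 200 over each array once the highest and lowest 2% of probe sets are left out, the mark of a single scaling factor per array, so nothing beyond that factor makes the arrays comparable. Detection calls and scanner files were not used here, so that whether a probe set was detected on an array is not given. The titles number the animals 1 to 3 within each genotype and call them biological replicates.

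Signals were transformed as log2(signal + 16) with no further normalization. The added 16 units keep dim probe sets from dominating and understate the changes of probe sets with low signal. All fold changes of tests are on this scale, while means ± SD are of the signals themselves. Of 45101 probe sets, 64 control probe sets were left out, and the rest were tested if their mean signal over the 6 arrays was above the 40th percentile of all probe sets, 37.8, leaving 26995. Gene names came from the platform annotation: 34945 probe sets have 1 gene symbol, 932 have several and 9160 are not listed with a gene. Of the single-gene probe sets, 34741 matched the NCBI gene table of assembly GRCm38.p6 by Entrez identifier, and 0 symbols changed. No probe set with several symbols was given a name. The table was used only for names and for which genes neighbour each other.

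The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. For counts of genes and for lists, each gene was represented by its single-gene probe set with the highest mean signal, which gave 12529 genes. Of 5798 genes with at least 2 tested probe sets, 8 had calls in both directions. Exact two-sided permutation tests were run for the Esrrg probe sets, where 3 arrays against 3 can give no p below 0.1. The 24 gene lists, with 524 members, of which 28 had no single-gene probe set, were written before the data were examined, as were the design, the alternatives and the rule for the genes named. Lists were tested with camera at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 24 lists. Of the 12 lists called, those for the respiratory chain, the tricarboxylic acid cycle and mitochondrial ribosomal proteins also passed with an estimated correlation. For mitochondrial ribosomal proteins that estimate was 0.00183, below the preset, yet the camera adjusted p went from 1.79e-08 to 0.0457. For secreted angiogenic factors it was -0.03, with adjusted p of 0.00306 and 0.132. This setting therefore changed more than the correlation used, and a lost call is no measure of correlated genes. The rotation test fry, which asks whether a list's genes move one way and not whether they differ from other genes, called 10.

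The named genes are all Esrrg probe sets, the 4 adult myosin heavy chain genes, the 10 largest rises and 10 largest falls among genes that passed with non-overlapping genotypes, and 2 genes per list, those with the largest absolute change among members that passed (1 where a single member passed) or, where none passed, those with the smallest p. Other genes are said to have been chosen after their values were seen.

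The test was tried on simulated data with the real arrays' means, 26995 probe sets and 3 arrays per group. Each probe set's real spread was drawn toward the median spread, and fewer probe sets were changed than were called in the data. In this setting the test recovered 69 of 100 probe sets changed 2-fold and 94 of 100 changed 4-fold. Of 179 calls, 16 (8.94%) were unchanged probe sets. The list test called 0 lists with nothing shifted and called the list shifted by 0.5. The simulated genes varied independently of each other, while the estimated correlation within the real lists reached 0.80. The simulation therefore cannot show how often the list test calls lists of correlated genes wrongly. Alternatives to the added constant, filter, scaling, variance model, array weights, replicate block, probe set choice and arrays used were run, including each array left out in turn. A comparison of 2 arrays against 2, without wild-type 3 and transgenic 3, was added after seeing the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.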

Results

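Transcript levels were measured on Affymetrix arrays in quadriceps muscle, a thigh muscle of mainly fast fibres in the mouse, from 8-week-old male C57/BL6 animals. The 3 wild-type and the 3 transgenic arrays each came from a separate biological replicate according to the sample titles. The transgenic animals carried ERRγ, an orphan nuclear receptor encoded by Esrrg that binds the promoters of many genes of oxidative metabolism, under the α-skeletal actin promoter, which is active in skeletal muscle fibres. The comparison of genotypes asks how muscle gene expression differs when this receptor is present at a high level. Each array gave a signal for 45101 probe sets, and its 2% trimmed mean was 200. The median signal ran from 52.1 to 56.3 in the wild-type arrays and from 57.1 to 61.9 in the transgenic arrays. Spearman correlations over the tested probe sets were 0.935 to 0.955 within a genotype and 0.906 to 0.930 between genotypes. The first principal component, with 44.1% of the variance, separated the genotypes. The ratio of 3′ to 5′ signal for Gapdh lay between 0.790 and 0.830 on all arrays, and that for Actb between 0.940 and 1.23. The number of arrays, 3 per genotype, limits the precision.

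Esrrg was the gene with the largest rise among the 12529 genes tested. The probe set with its highest signal gave 52.2 ± 24.9 (SD, n = 3) in wild-type and 13644 ± 876.6 (SD, n = 3) in transgenic muscle, a ratio of means of 261. On the log2(signal + 16) scale the difference was 7.72 (SE 0.24, limma adjusted p = 1.71e-07), and the ranges, 24.1 to 71.6 and 12697 to 14427, did not overlap. The exact two-sided permutation test of this probe set gave p = 0.1, the smallest value that 3 arrays against 3 allow. The other Esrrg probe sets gave 104.9 ± 18.2 and 145.3 ± 38.5, and 38.5 ± 1.6 and 53.3 ± 4.6 (SD, n = 3 each, wild-type first), and did not pass the test, with limma adjusted p = 0.284 and 0.443. A probe set in the 3′ untranslated region can lie outside a transgene. Where these probe sets lie could not be checked, so they were not used to check the labels.

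Beyond the transgene, the lists for the respiratory chain, the tricarboxylic acid cycle and mitochondrial ribosomal proteins passed camera upward at the preset and at an estimated correlation. The slow-fibre list passed at the preset correlation but not at an estimated one (adjusted p = 0.218). Smox and Prkag3 were among the 10 largest falls. Myosin heavy chain IIa (Myh2), the motor of fast oxidative fibres, rose 6.03-fold, from 1634 ± 548.4 to 9544 ± 829.4. Ankrd2 and Csrp3, stretch-responsive proteins of the sarcomere that are abundant in slow fibres, rose 9.58-fold and 7.85-fold. Smox, spermine oxidase, fell by 4.63 on the log2 scale, from 7444 ± 2340 to 275.0 ± 36.4, and Prkag3, the γ3 subunit of AMP-activated protein kinase found in fast glycolytic muscle, fell by 3.11, from 2857 ± 325.4 to 319.0 ± 71.2 (SD, n = 3 in each case). Of 26995 probe sets tested, 3115 (11.5%) changed at a limma adjusted p under 0.05, 1721 higher and 1394 lower in transgenic muscle. By gene, 1679 of 12529 changed, 958 higher and 721 lower, and 223 rose and 160 fell at least 2-fold.

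The direction of the probe set calls depends on how the arrays are scaled. With the scaling as deposited, 55.2% of the calls were higher in transgenic muscle, and with each array scaled to a common median the share was 44.0%, from 1372 probe sets higher in transgenic and 1747 probe sets lower in transgenic muscle. Signals of the genotypes did not overlap at 8360 tested probe sets (31.0%), where chance gives 10%. The count of changed probe sets was 1705 without wild-type 1, 1875 without wild-type 2, 1916 without transgenic 1 and 2073 without transgenic 2. With all arrays but without the intensity trend in eBayes it was 1584.

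The 10 largest rises after the fixed rule were Esrrg, BC048679, Atp1b4, Ankrd2, Myl2, Fads6, Csrp3, Il15, Ak4 and P2ry1. BC048679, a transcript without an assigned function, went from 83.3 ± 14.7 to 1357 ± 193.5, a rise of 3.79 (SE 0.16). Atp1b4, which encodes a member of the sodium-potassium ATPase β subunit family, went from 61.2 ± 18.9 to 834.6 ± 213.3, and Fads6, a member of the fatty acid desaturase family, from 114.4 ± 4.1 to 1023 ± 73.8. Il15, a cytokine that muscle expresses, went from 83.3 ± 33.8 to 646.2 ± 50 (log2 difference 2.80, SE 0.24, limma adjusted p = 6.71e-05). Ak4, a mitochondrial adenylate kinase, rose 6.87-fold. P2ry1, a purinergic receptor, went from 7.1 ± 3.5, far below the added 16 units, to 136.4 ± 46.2, so that its log2 difference of 2.68 understates the ratio. Myl2, the slow ventricular regulatory light chain, rose by 3.11 (SE 0.52, limma adjusted p = 0.00366), and did not pass with robust eBayes (adjusted p = 0.0630).

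The 10 largest falls were Smox, Ighm, BC023105, Prkag3, Rab40b, Gdap1, Npnt, Cpeb1, 1700001O22Rik and Htra4. BC023105 went from 2196 ± 461.7 to 211.5 ± 51.3, Rab40b, a small GTPase of the Rab family, from 888.0 ± 53.9 to 101.3 ± 12.6, and Gdap1, a protein of the outer mitochondrial membrane, from 820.2 ± 93.0 to 98.7 ± 12.1. Cpeb1, which binds cytoplasmic polyadenylation elements, fell by 2.71 (SE 0.16) and Npnt, an extracellular matrix protein, fell by 2.77 (SE 0.34). The transcript 1700001O22Rik was at 15.9 ± 3.6 and the protease gene Htra4 at 20.8 ± 15.8 in transgenic muscle, near the added 16 units. The fall of Ighm, the immunoglobulin μ chain, rests on 2 of its 11 probe sets, which went from 1950 ± 460.4 to 165.1 ± 3.8 and from 281.6 ± 34.1 to 47.4 ± 39.0. Another rose, from 46.0 ± 22.2 to 121.3 ± 28.5 (limma adjusted p = 0.0286), and the rest of its 8 tested probe sets did not pass. The B cell genes Cd79a, Cd79b and Ms4a1, chosen after their values were seen, had no signal above 54.4 on any array.

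**Figure D1:**
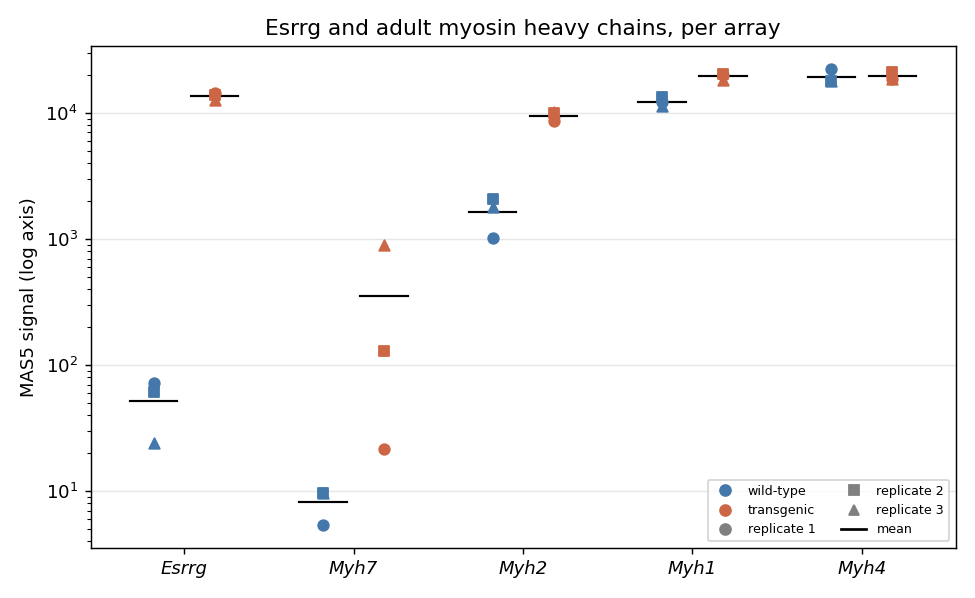
MAS5 signal on a log axis for Esrrg and the 4 adult myosin heavy chain genes, with a point for each array, a symbol for each replicate and a bar for the mean of each genotype (n = 3). Esrrg and Myh2 separate the genotypes widely, Myh4 overlaps at 17940 to 22426, and Myh7 ranges from 21.4 to 900.8 across the transgenic arrays.

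Among the adult myosin heavy chains, Myh2 and Myh1 rose. The difference for Myh4 at its brighter probe set was smaller than the spread between replicates. Myh2, of type IIa fibres, differed by 2.59 (SE 0.21, limma adjusted p = 5.68e-05). Myh1, of type IIx fibres, differed by 0.67 (SE 0.09, limma adjusted p = 0.00129), from 12310 ± 960.5 to 19522 ± 1125. The other Myh1 probe sets rose by 0.72 (SE 0.11) and, at the dimmest, by 1.85 (SE 0.31). Myh4, of type IIb fibres, gave 19442 ± 2584 and 19519 ± 1510 at that probe set, a log2 difference of 0.01 (SE 0.11). Its dimmer probe set gave 15275 ± 1974 and 13312 ± 808.4, a log2 difference of -0.19 (SE 0.11). It overlapped between the genotypes and did not pass either (limma adjusted p = 0.302). Whether signals this bright still follow a change in transcript level was not tested, so a small difference in Myh4 could be missed. Myh7, the slow type I isoform, gave 5.4, 9.6 and 9.7 in wild-type and 21.4, 129.1 and 900.8 in transgenic muscle, with a log2 difference of 2.82 (SE 0.86) that did not pass (limma adjusted p = 0.0606). It passed without transgenic 1 (adjusted p = 0.00777), with the replicate block (adjusted p = 0.0243) and with offset 1 in place of 16 (adjusted p = 0.0420). Sequences of Myh1, Myh2 and Myh4 are close, and probe sets can cross-hybridise between them, so the share of each isoform is uncertain.

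The list for contraction and calcium handling in slow fibres had a positive median and passed camera, but not with an estimated correlation. Of 15 tested, 6 rose, 0 fell and 9 did not pass, and the median log2 difference was 1.84. The risers were Ankrd2 (3.26, SE 0.26), Myl2 (3.11), Csrp3 (2.97), Tnnt1, slow troponin T (2.48, SE 0.57), Casq2, the slow and cardiac calsequestrin (2.10, SE 0.16) and Myoz2 (1.84, SE 0.36). Counted with p adjusted over the list alone, 11 rose and 0 fell. The camera adjusted p was 4.40e-07, and the adjusted p = 0.218 with an estimated correlation. Transgenic 3 stood apart in this group, with a signal of 1954 for Myl2 against 302.8 and 395.7 in the other transgenic arrays, and 1478 against 91.1 and 243.0 for Myl3. Without transgenic 3 the median was 1.09, 6 members rose, and the camera adjusted p was 1.88e-05, and without transgenic 1, 10 members rose. Of 15 fast-fibre genes tested, Myh1 rose, Ampd1, muscle AMP deaminase, fell by 0.35, and 13 did not pass, with the same counts when adjusted over the list alone. The adjusted p of Ampd1 lay between 0.0806 and 0.123 without wild-type 1, without wild-type 2 or without any 1 of the transgenic arrays. Their median of 0.02 turned to -0.08 after quantile normalization, with 3 members lower, to -0.04 after median scaling, to -0.06 without wild-type 3 and to -0.02 without wild-type 2 or transgenic 2, and was 0.12 without wild-type 1 and 0.04 without transgenic 3. The median and mean were positive, camera gave the direction down with an adjusted p of 0.783, and fry gave up with 0.929.

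**Figure D2:**
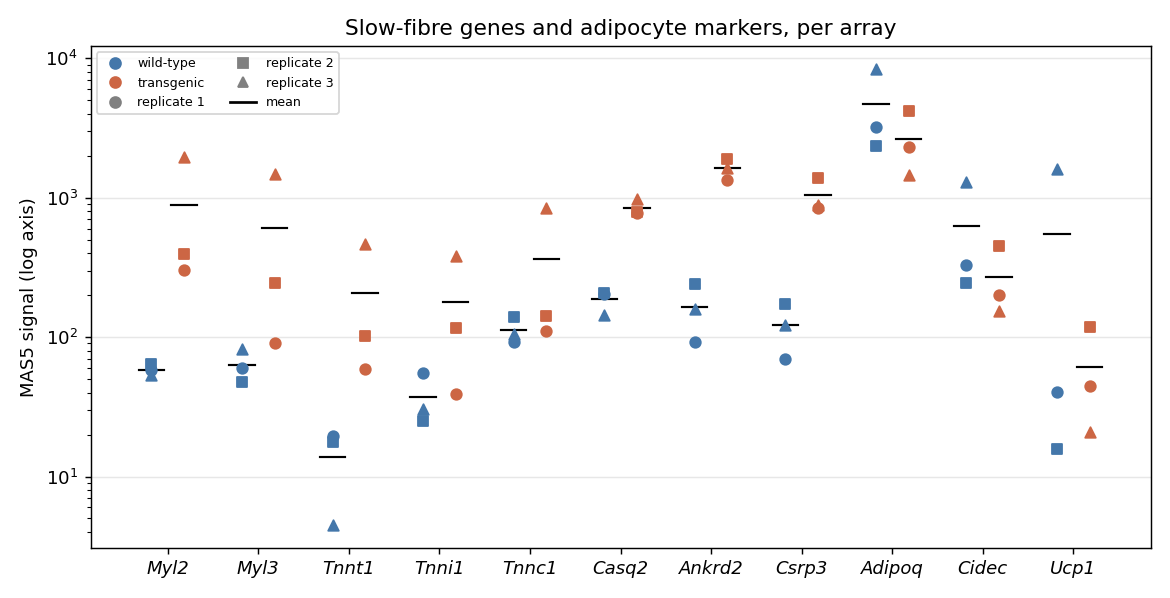
MAS5 signal on a log axis for 8 slow-fibre genes and the adipocyte genes Adipoq, Cidec and Ucp1, with a point for each array, a symbol for each replicate and a bar for the mean of each genotype (n = 3). Transgenic 3 lies highest for Myl2, Myl3, Tnnt1, Tnni1 and Tnnc1, and wild-type 3 lies highest for Adipoq, Cidec and Ucp1.

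The respiratory chain, tricarboxylic acid cycle and mitochondrial ribosome lists had positive medians and passed camera. A smaller share of members rose in the ribosomal list than in the others, a difference that was not tested. In the respiratory chain and ATP synthase, 55 of 74 tested genes rose, 0 fell and 19 did not pass, with a median log2 difference of 0.42. Examples are Uqcrq of complex III, from 3512 ± 256.7 to 7405 ± 44.4, and Sdhb of complex II, from 7533 ± 340.4 to 12798 ± 1428. In the tricarboxylic acid cycle and pyruvate dehydrogenase group, 13 of 18 rose, 0 fell and 5 did not pass, with a median of 0.39. Here Idh2, mitochondrial isocitrate dehydrogenase, rose 2.90-fold (log2 difference 1.53, SE 0.12), and Idh3b rose by 0.76, with an adjusted p of 0.0182 that was 0.0677 without wild-type 1, 0.0562 without wild-type 2 and 0.0636 without transgenic 2. The other Idh3b probe sets, both dimmer, did not pass, at -0.50 and 0.19. Adjusted over the list alone, 64 and 17 genes of these groups rose and 0 fell. Their camera adjusted p were 4.04e-24 and 8.37e-09, and each had an adjusted p = 0.0495 with an estimated correlation, under the threshold. Among mitochondrial ribosomal proteins, 25 of 73 rose, 1 fell and 47 did not pass, with Mrpl14 at 1.27 (SE 0.13) and Mrpl19 at 0.88 (SE 0.14) at 1 of its 3 tested probe sets, while the others did not pass, at -0.16 and 0.29 (adjusted p = 0.589 and 0.224). The median was 0.28, 31 rose and 2 fell when adjusted over the list alone, the camera adjusted p was 1.79e-08, and the adjusted p = 0.0457 with an estimated correlation. The respiratory chain count fell to 35 without wild-type 2 and without transgenic 1. The tricarboxylic acid cycle count was 7 after median scaling and without transgenic 2 or transgenic 3, 6 without transgenic 1, and 4 without wild-type 1 or wild-type 2. The ribosomal count was 13 to 15 without wild-type 1, wild-type 2, transgenic 1 or transgenic 2, and 0 fell under each of these. All 3 lists passed camera at the preset correlation under each of these settings. Camera with an estimated correlation was not run with an array left out or after rescaling.

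Fatty acid uptake and oxidation had the largest share of risers among the 24 lists: 25 of 28 tested genes rose, 0 fell and 3 (Hadhb, Cd36 and Slc27a1, chosen after their values were seen) that did not pass at log2 differences of 0.43, 0.68 and 0.74. Fabp3, the heart-type fatty acid binding protein, went from 3153 ± 763.4 to 11532 ± 596.2, and Acaa2, a thiolase of mitochondrial β-oxidation, from 1447 ± 709.9 to 5026 ± 449.7. The median was 0.97, all 28 rose when adjusted over the list alone, the camera adjusted p was 1.19e-20, and the adjusted p = 0.132 with an estimated correlation. Of 18 genes for branched-chain amino acid and ketone body catabolism, 7 rose, 0 fell and 11 did not pass, with a median of 0.39. Bdh1, which interconverts ketone bodies, rose by 1.31 (SE 0.27), with an adjusted p of 0.0521 without transgenic 2 and 0.0513 without transgenic 3, and Ivd, of leucine catabolism, by 0.89 (SE 0.16). Adjusted over the list alone, 10 rose and 0 fell. The camera adjusted p was 9.37e-06, and the adjusted p = 0.454 with an estimated correlation. This list did not pass with fry either (adjusted p = 0.0878). Wild-type 3 lay above the mean of the other wild-type arrays in both groups, by a median of 0.49 and 0.39, and without it 28 and 13 members rose. Adipocyte markers on this array also lay higher, by a median of 1.73, and a link between these differences was not tested. Without transgenic 2, 4 of the branched-chain amino acid and ketone body genes rose.

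Glycolysis and glycogen metabolism went both ways. Of 18 tested genes, 2 rose, 4 fell and 12 did not pass. Fbp2, muscle fructose bisphosphatase (1.14, SE 0.16), and Hk2, hexokinase 2 (0.51, SE 0.10), rose. Pfkfb3, which makes an activator of phosphofructokinase (-1.85, SE 0.25), and the phosphorylase kinase subunits Phka1 (-1.22, SE 0.12), Phkb (-0.93, SE 0.11) and Phkg1 (-0.64, SE 0.16) fell. The names Fbp2, Hk2, Phkb and Phkg1 were chosen after their values were seen. Adjusted over the list alone, 3 rose and 4 fell. The median was -0.14, the camera adjusted p was 0.219, and 0.687 with an estimated correlation. The list passed after quantile normalization (adjusted p = 0.0261) and without wild-type 3 (adjusted p = 0.0152), with 7 members lower in the former case, and in the 2 against 2 comparison added after seeing the data (adjusted p = 0.0463). The median was -0.05 without wild-type 1.

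The 3 vascular lists had positive medians and passed camera at the preset correlation, but not at an estimated one. Among secreted angiogenic factors, 4 of 15 rose, 1 fell and 10 did not pass. Fgf1 went from 188.2 ± 27.5 to 776.1 ± 145.7 and Vegfa from 752.0 ± 63.9 to 1884 ± 423.3, and Vegfb (1.21) and Angpt1 (1.19) rose too, while Vegfd, a factor that also acts on lymphatic vessels, fell by 0.94 (0 members fell without wild-type 1, wild-type 2, transgenic 1 or transgenic 3). The names Vegfb, Angpt1 and Vegfd were chosen after their values were seen. Adjusted over the list alone, 9 rose and 1 fell. The median was 0.58, the camera adjusted p was 0.00306, and the adjusted p = 0.132 with an estimated correlation. Of 18 endothelial cell markers, 11 rose, 0 fell and 7 did not pass, with a median of 0.70. Esam, an adhesion molecule of endothelial junctions, went from 472.0 ± 35.1 to 1204 ± 79.1, and Gpihbp1, which carries lipoprotein lipase on capillaries, from 620.2 ± 173.1 to 1263 ± 110.7. Adjusted over the list alone, 14 rose and 0 fell, and 6 rose without wild-type 1 or transgenic 3 and 7 without transgenic 2. The camera adjusted p was 1.03e-08, and the adjusted p = 0.132 with an estimated correlation. Of 10 pericyte and vascular smooth muscle markers, Kcnj8 (0.82, SE 0.13) and Rgs5 (0.76, SE 0.10) rose, 0 fell and 8 did not pass, with 5 and 1 when adjusted over the list alone and a median of 0.34. The camera adjusted p was 0.0142, and the adjusted p = 0.399 with an estimated correlation. Without transgenic 3 the adjusted p of this list was 0.0740, and without wild-type 1, 3 members rose.

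Leukocyte and fibroblast markers had negative medians. Of 16 macrophage and other leukocyte markers, Lyz2, lysozyme, fell by 0.55 (SE 0.13), 0 rose and 15 did not pass. The adjusted p of Lyz2 lay between 0.0591 and 0.109 without wild-type 1, wild-type 2, transgenic 1 or transgenic 3. The median was -0.33, 0 rose and 1 fell when adjusted over the list alone, the camera adjusted p was 0.0105, and the adjusted p = 0.399 with an estimated correlation. After median scaling and without transgenic 2, 2 members fell. The camera adjusted p was 0.0661 without wild-type 3 and 0.0702 without transgenic 3. This list did not pass with fry either (adjusted p = 0.137). Of 15 fibroblast and extracellular matrix markers, Dpt, dermatopontin, fell by 0.48 (SE 0.14), 0 rose and 14 did not pass, and all 15 had negative differences. Dpt did not pass without any 1 array other than wild-type 2, with adjusted p from 0.0620 to 0.148, and 3 members fell after median scaling. The median was -0.15 (-0.29 after quantile normalization, -0.26 without wild-type 3 and -0.24 without transgenic 2), 0 rose and 3 fell when adjusted over the list alone, the camera adjusted p was 0.00400, and the adjusted p = 0.132 with an estimated correlation.

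Of 10 adipocyte markers, Acvr1c fell by 1.67 (SE 0.37), 0 rose and 9 did not pass, with the same counts when adjusted over the list alone. The other 2 tested probe sets of Acvr1c overlapped between the genotypes and did not pass, at -0.19 and -1.01 (adjusted p = 0.753 and 0.185). Acvr1c had an adjusted p of 0.0730 without wild-type 1 and 0.0703 without wild-type 3. The median was -0.83, the camera adjusted p was 0.0428, and the adjusted p = 0.537 with an estimated correlation. Wild-type 3 carried this difference: its Adipoq signal was 8412 against 3217 and 2367 in the other wild-type arrays, and its Ucp1 signal, the uncoupling protein of brown fat, 1596 against 40.5 and 15.7. Without wild-type 3 the median was -0.14 with a camera adjusted p of 0.638, without transgenic 3 it was -0.45 with 0.179, without transgenic 1 it was -0.67 with 0.0985, and without transgenic 2 it was -1.28 with 0.00551. The list also did not pass with offset 1, the 60th percentile filter, median scaling, array weights, eBayes without a trend or fry, with adjusted p from 0.0510 to 0.408. Adipoq, Ucp1 and Fabp4 did not pass, at -0.73 (SE 0.44), -1.09 (SE 1.15) and 0.05 (SE 0.17).

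Regulators of oxidative metabolism did not shift as a list, although single members changed strongly. Of 26 tested, 6 rose, 3 fell and 17 did not pass, and 7 rose and 3 fell when adjusted over the list alone. Perm1, a muscle regulator downstream of PGC-1 and ERR, rose 3.05-fold from 1094 ± 153.0 to 3357 ± 238.5, and Ppara, Ppargc1b, Sirt3, Tfam and Prkag1 rose by 0.47 to 1.36. With Prkag3, the AMP-activated protein kinase subunit Prkab2 (-0.79) and the transcription factor Mef2c (-0.38) fell. These genes other than Perm1 and Prkag3 were chosen after their values were seen. Ppargc1a, the coactivator PGC-1α, also chosen after its values were seen, did not pass at any of its 5 probe sets. Without transgenic 2, 3 members rose, without wild-type 1, 4 rose, and without any 1 array other than wild-type 3, 2 fell. The list median was 0.12 (0.25 without wild-type 3 and 0.06 after median scaling), the camera adjusted p was 0.332, and 0.537 with an estimated correlation.

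**Figure D3:**
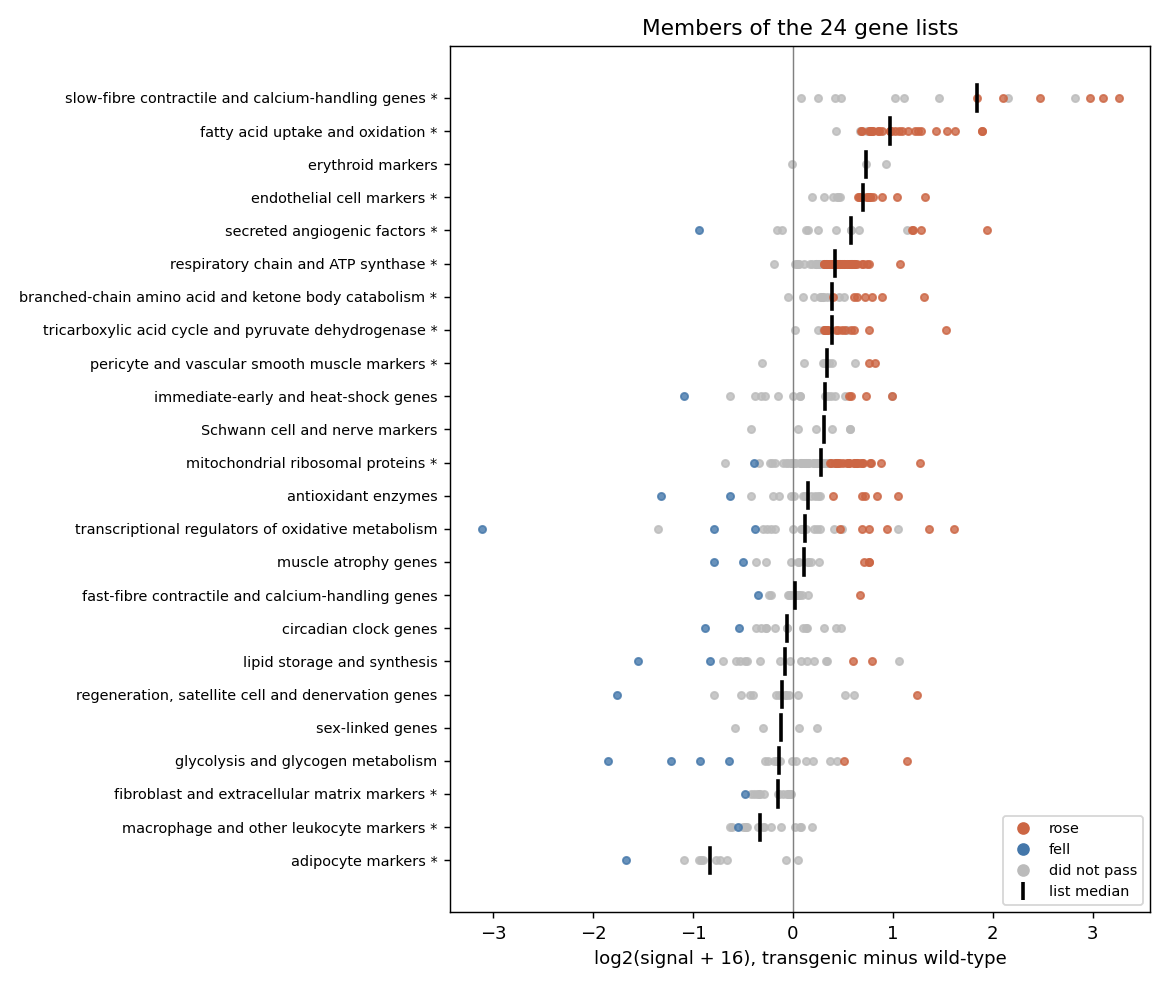
Log2(signal + 16) difference, transgenic minus wild-type, for each tested member of the 24 gene lists, coloured by whether it rose, fell or did not pass at a limma adjusted p under 0.05, with a bar at the list median. An asterisk marks the 12 lists with a camera adjusted p under 0.05. Slow-fibre genes have the highest median, 1.84, and adipocyte markers the lowest, -0.83, which was -0.14 without wild-type 3.

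The remaining lists did not pass the camera test. In lipid storage and synthesis, 2 of 18 rose, 2 fell and 14 did not pass: Plin3 (0.79) and Acacb (0.60) rose, while Srebf1, a lipogenic transcription factor, fell by 1.55 (SE 0.15) and Scd2 fell by 0.83 (SE 0.13). The names Plin3 and Acacb were chosen after their values were seen. The median was -0.08, with 3 up and 2 down when adjusted over the list alone and a camera adjusted p of 0.783. Without wild-type 3, whose median in this list lay 0.88 above the other wild-type arrays, it was 0.26 with 5 genes up. It was 0.08 without transgenic 1 and 0.04 without transgenic 3, and -0.36 without transgenic 2, -0.23 without wild-type 1, -0.17 without wild-type 2, and -0.13 after quantile normalization or median scaling. Among antioxidant enzymes, 5 of 18 rose, 2 fell and 11 did not pass. Cat, catalase, rose by 1.05 (SE 0.27), with adjusted p between 0.0723 and 0.112 without wild-type 1, wild-type 2 or any 1 of the transgenic arrays, and Gclm, of glutathione synthesis, fell by 1.32 (SE 0.14). Txn2 (0.84), Sod2 (0.72), Prdx2 (0.69) and Glrx (0.40) rose and Gclc (-0.63) fell, names chosen after their values were seen. The count of risers was 3 without any 1 array other than wild-type 3, and 1 member fell without wild-type 2. This list had 5 up and 3 down when adjusted over the list alone, a median of 0.15 (0.09 after median scaling and 0.10 without transgenic 2) and a camera adjusted p of 0.332.

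Atrophy genes went both ways, with 3 of 14 up, 2 down and 9 not passing. Trim63, the ubiquitin ligase MuRF1, fell by 0.79 (SE 0.12) and Foxo3 rose by 0.77 (SE 0.16, with an adjusted p of 0.0544 in the 2 against 2 comparison added after seeing the data), and Gadd45a (0.76) and Klf15 (0.71) rose and Ctsl (-0.50) fell, the last 3 chosen after their values were seen. The list had 3 up and 3 down when adjusted over the list alone, a median of 0.11 (0.05 after median scaling and 0.16 without transgenic 3) and a camera adjusted p of 0.858. Without transgenic 1, 1 member rose and the median was -0.00682, and 2 rose after median scaling and without wild-type 1, transgenic 2 or transgenic 3. In the regeneration, satellite cell and denervation list, Chrna1, an acetylcholine receptor subunit, rose by 1.24 (SE 0.15), Myh8, perinatal myosin, fell by 1.76 (SE 0.26) and 12 of 14 did not pass, with 2 up and 2 down when adjusted over the list alone, a median of -0.11 and a camera adjusted p of 0.332. That median was -0.21 after quantile normalization, -0.23 without wild-type 3, -0.18 without transgenic 2 and -0.17 without transgenic 3, and 2 fell after median scaling. In the immediate-early and heat-shock list, 4 of 19 rose, 1 fell and 14 did not pass. Atf3 rose by 0.99 (SE 0.26), with adjusted p between 0.0545 and 0.138 without any 1 wild-type array, transgenic 1 or transgenic 2, and Hsph1, a heat-shock chaperone, fell by 1.09 (SE 0.15). Btg2 (0.73), Jun (0.58) and Ddit3 (0.56) rose, names chosen after their values were seen. Without wild-type 1 or transgenic 1, 0 rose, without wild-type 2 or transgenic 2, 1 rose, and without transgenic 3, 2 rose. The list counts were the same when adjusted over the list alone, the median was 0.32 (0.15 without wild-type 1 and 0.21 after quantile normalization) and the camera adjusted p 0.332.

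Among 15 circadian clock genes, Bhlhe41 (-0.88, SE 0.22) and Bhlhe40 (-0.54, SE 0.12) fell, 0 rose and 13 did not pass, with the same counts when adjusted over the list alone, a median of -0.06 and a camera adjusted p of 0.342. The adjusted p of Bhlhe41 lay between 0.0533 and 0.109 without any 1 wild-type array, transgenic 1 or transgenic 2, and that of Bhlhe40 was 0.0719 without transgenic 1 and 0.0569 without transgenic 3. The list median turned to 0.02 without transgenic 2, was -0.02 without transgenic 3, and ran from -0.10 to -0.23 after either rescaling and without wild-type 2, wild-type 3 or transgenic 1. Without wild-type 3, 1 member rose. No member passed in the lists for Schwann cell and nerve (6 tested), erythroid (3 tested) or sex-linked genes (4 tested). Mag and Sox10 of nerve gave 0.57 (SE 0.22) and 0.39 (SE 0.19), Alas2 and Hbb-b2 of red cells 0.73 (SE 0.27) and 0.93 (SE 0.36), and the Y-linked Uty and Kdm5d -0.58 (SE 0.28) and -0.30 (SE 0.17). Hbb-b2 passed without wild-type 1, with an adjusted p of 0.0448. Adjusted over the list alone, 0 nerve, 2 erythroid and 0 sex-linked genes rose and 0 fell. Their medians were 0.31, 0.73 and -0.12, with camera adjusted p of 0.332, 0.332 and 0.505, and fry called the nerve list higher (adjusted p = 0.0179). The sex-linked median was -0.25 without transgenic 3, -0.21 without wild-type 2, -0.06 without wild-type 1 and -0.00188 without transgenic 2.

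Genes named by the rule are given at the probe set with the highest mean signal, and other tested probe sets of some did not pass. Beside those given above, this holds for Npnt (-0.12 and -0.27), Gdap1 (-0.36), Uqcrq (-0.01 and 0.32), Idh2 (0.31), Ivd (0.68), Scd2 (-0.56 and -0.73), Cat (0.65), Foxo3 (0.33) and Bhlhe41 (-0.58).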

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

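The tests of muscle fibre RNA, of sample identity, of slow fibres in the sampled piece and of the general mitochondrial rise were chosen after the results were seen, and the others were written before. After a first run, the endothelial and Nnt tests were also held to passing their bounds by more than their error. The probe sets of the array's control set for the transferrin receptor, Tfrc, which takes up iron, lay above all wild-type arrays on all transgenic arrays, although control probe sets were outside the comparisons. Their log2 differences were 1.10 (SE 0.13), 0.81 (SE 0.16) and 1.38 (SE 0.14) for the 3′, 5′ and middle parts of the transcript, with limma p adjusted over the 19 mouse control probe sets of 3.73e-05, 0.00228 and 2.77e-05. The 3 regular Tfrc probe sets also rose, by 0.97 to 1.34. Of the same 19, 6 were lower on all transgenic arrays with an adjusted p under 0.05: the 4 for Pcx, pyruvate carboxylase (-0.79 to -1.29), the middle part of 18S ribosomal RNA (-0.77, SE 0.16) and the middle part of Actb (-0.30, SE 0.10). The 3′ and 5′ parts of 18S and Actb did not pass, at -0.02 and -0.18 for 18S and 0.03 and -0.14 for Actb. What lowered the middle parts was not tested.

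Endothelial cell markers were higher in transgenic muscle, with a median log2 difference of 0.70 (camera adjusted p = 1.03e-08, and adjusted p = 0.132 with an estimated correlation). Quantile normalization left a median of 0.65 (0.62 to 0.75 with any array left out), which argues against single-factor array scaling. The endothelial median lay 0.85 above the higher of the fibroblast and leukocyte medians (0.77 to 0.98 with any array left out). That argues against a lower share of muscle fibre RNA as the only source, if expression within fibroblasts and leukocytes was unchanged. These medians were known when the bound was set. A larger share of endothelial cells may be the explanation: 3 of 18 members (Esam, Tek and Vwf) had a 95% interval that left out the median, between the bounds set for and against a larger share of endothelial cells, so it cannot be told apart from a change of expression within them. The genotype is the biological difference in the design, and how it would act on vessels was not tested here.

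Slow-fibre sarcomere genes were far higher in transgenic 3 than in transgenic 1 and 2, by a median of 2.44 over Myh7, Myl2, Myl3, Tnnt1, Tnni1, Tnnc1 and Tpm3, the last of which did not take part (-0.07). The median over all tested genes was -0.0151, so the scaled values held no whole-array shift. Scaling each array to a trimmed mean of 200 largely fixed that outcome in advance. No conclusion is drawn from it about a shift that arose before scaling. A swap with a wild-type sample is argued against by the Esrrg signal of transgenic 3, 89.9% of the mean of the other transgenic arrays. Another muscle of a transgenic animal under this label could also have high Esrrg, so this signal cannot address that. More slow fibres in the piece of muscle sampled may account for the pattern. The other 8 slow-fibre members lay higher by a median of 0.34. That was above 99.9% of 10000 random lists matched on signal but below the 0.50 set for support. More slow fibres therefore stay open as an explanation, beside a difference between the animals in their response to the transgene, which was not tested.

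Nnt, the transhydrogenase of the inner mitochondrial membrane, was chosen after its values were seen and differed by 2.24 (SE 0.15), from 696.6 ± 118.9 to 3350 ± 536.0 (SD, n = 3). Background knowledge is that the C57BL/6J substrain carries a deletion in Nnt, so a substrain difference between the groups is a candidate explanation. A chromosome segment of another strain around Nnt is a further candidate. Of 17 tested genes within 10 places of Nnt in the gene order of GRCm38.p6, 2 (11.8%, exact 95% interval 1.46% to 36.4%) were called. Among all placed genes 13.4% were called, so the interval is too wide to decide on a segment. The neighbours cannot address a substrain difference limited to Nnt, since that need not change them. As part of the general rise of mitochondrial genes, 2.24 lies above the highest of 120 members of the respiratory chain, tricarboxylic acid cycle and fatty acid lists, Fabp3 at 1.89 (SE 0.15). The gap of 0.35 (SE 0.21) is larger than its standard error but within its 95% half-width of 0.47. None of these explanations is settled.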

How the results depend on the processing

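The comparison of 2 arrays against 2 was added after seeing the data; all other alternatives were planned. Numbers of probe sets changed, probe sets higher in transgenic and probe sets lower in transgenic muscle were 3115, 1721 and 1394 in the report and 1584, 951 and 633 without the intensity trend in eBayes, and testing 1 probe set per gene, fewer probe sets, gave 1822, 1032 and 790. At an adjusted p under 0.10, 2103 were lower. With any 1 array left out, the count ran from 1705 to 3301, with 1028 to 1783 higher and 677 to 1518 lower. It was 1705 without wild-type 1, 1875 without wild-type 2, 1916 without transgenic 1, 2073 without transgenic 2, 2329 without transgenic 3 and 3301 without wild-type 3. Fewer samples were tested in each, and beyond that the causes were not tested. The 2 against 2 comparison called 2900, of which 2279 were shared with the report. Quantile normalization and median scaling moved the median of all tested probe sets from 0.05 to -0.00316 and -0.01.

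With the correlation estimated per list, 3 of 24 lists changed against 12, and 10 by fry. All other settings gave 9 to 13, with 9 without transgenic 3. Of 455 alternative list medians 410 kept their side of the threshold and direction, 25 lost and 4 gained a call and 16 reversed. Of 1083 alternative values for named genes, 1012 kept both, 60 lost and 4 gained a call and 7 reversed, all of Myh4. The called adipocyte median turned to 0.17 in the 2 against 2 comparison, and the other reversals were of medians and values that passed on neither side. The fast-fibre median, 0.02 in the report, was -0.0767 after quantile normalization, -0.0396 after median scaling, -0.0154 with array weights, -0.0537 with the mean of the gene's probe sets and -0.0215 in the 2 against 2 comparison. With any 1 array left out it ran from -0.0613 to 0.118, below 0 without wild-type 2, wild-type 3 or transgenic 2. The lipid storage median, -0.08, was 0.43 in the 2 against 2 comparison and ran from -0.36 to 0.26 with any 1 array left out, above 0 without wild-type 3, transgenic 1 or transgenic 3. With any 1 array left out the atrophy median ran from -0.00682 to 0.16 and the circadian one from -0.23 to 0.0247, and with the mean of the gene's probe sets the sex-linked one was 0.0350. Myh4, 0.01, was -0.0622 after quantile normalization, -0.0439 after median scaling, -0.0154 with array weights and -0.0105 in the 2 against 2 comparison. With any 1 array left out it ran from -0.0521 to 0.118, below 0 without wild-type 2, wild-type 3 or transgenic 2. The causes were not tested. Calls of named genes were lost without the eBayes trend for Idh3b, Ampd1, Cat, Lyz2, Dpt, Bhlhe41 and Bhlhe40, without a filter for Ampd1, Cat, Dpt, Atf3 and Bhlhe41, with the replicate block for Ampd1 and Dpt, with robust eBayes for Cat and Myl2, and after quantile normalization for Dpt. The transgene target Esrrg passed in every setting run, at 6.90 to 8.14. Gene lists were not run with robust eBayes, which camera does not offer, and at the 60th percentile filter the erythroid list and 5 named genes had no tested probe set.

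The labels do not say whether a replicate number is shared between the genotypes. Deviations of same-numbered arrays correlated at 0.07, -0.08 and -0.02, so no pairing was seen, though so few arrays cannot exclude one. With the number as a replicate block, the count of probe sets changed was 2744, with 1521 probe sets higher in transgenic and 1223 probe sets lower in transgenic muscle. The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. In 1 of the 10 splits, the real one, as many probe sets changed, rose or fell: 3115 against at most 2 in another split, 1721 higher and 1394 lower against at most 1. Every other split mixes the genotypes within its groups, so the genotype difference widens the spread there and lowers the counts. Such counts do not show how many calls would arise without a genotype difference. For the gene lists 1 split, the real one, gave 12, and the highest count in another split was 11. In every other split each group holds more arrays of 1 genotype, so part of the genotype difference remains. The list counts therefore do not show how often camera with the preset correlation calls lists without a genotype difference. Dim probe sets limit what can be seen, since 21.8% to 24% of each array's signals lie below the added 16 units.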

Other observations

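The genes in this part other than Atp1b4 and Smox were chosen after their values were seen. In the sodium-potassium ATPase β subunit gene family, Atp1b1 rose at 4 probe sets, by 1.80 to 2.11. It did not pass at its dimmest (0.42, SE 0.24, limma adjusted p = 0.309). Atp1b2 fell by 2.27 (SE 0.13) and by 1.90 (SE 0.14) at its 2 probe sets. Atp1b4 rose by 3.46 (SE 0.23), and whether its product acts in the pump was not tested. Among polyamine genes other than Smox, Odc1, ornithine decarboxylase, fell from 3597 ± 891.9 to 739.1 ± 202.2 (SD, n = 3) at its brightest probe set. Azin1, an inhibitor of its antizyme, fell by 0.61 (SE 0.13) at its brightest probe set and by 0.70 (SE 0.13) at another, and did not pass at its dimmest (-0.55, adjusted p = 0.130), while Oaz1, Sat1 and Srm did not pass, at -0.02, -0.13 and 0.24. The heart-type lactate dehydrogenase Ldhb rose from 438.3 ± 123.6 to 2020 ± 143.1, and Ldha, the muscle type, did not pass (-0.16, SE 0.12).

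In creatine metabolism, Gamt, which makes creatine, fell from 473.6 ± 32.6 to 122.0 ± 5.9, mitochondrial creatine kinase Ckmt2 rose by 0.70 (SE 0.11), and the brighter probe set of Ckm did not pass (0.09, SE 0.11) while the dimmer one fell by 0.57 (SE 0.12). The Z-disc protein Actn2 rose from 1909 ± 428.1 to 8171 ± 421.1, and its fast-fibre relative Actn3 did not pass (-0.22, SE 0.09). Pcx, pyruvate carboxylase, fell by 1.30 (SE 0.24), and Fndc5, the precursor of irisin, rose by 1.72 (SE 0.20) and 1.44 (SE 0.15) at its 2 probe sets.

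A chromosome segment carried with the transgene or disturbed by its insertion could gather changed genes next to each other. The window of 20 neighbouring tested genes with the most calls held 9, and 1000 random reassignments of the calls had a median of 9 and a 95th percentile of 10. The count did not exceed chance. A segment with fewer changed genes would not be seen this way, so the bound set beforehand against a chromosome segment was too weak to exclude one, a judgement made after a first run.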
